A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

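Poly(A) RNA from 5 yeast samples was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The Ye6100 set, with 4 chips per sample, was used for 3 RNA samples and the single-chip S98 array for 2. The deposited values are intensities, 1 linear signal per probe set, made with MAS5, per the submitters' processing notes. The version, scaling target and genome build are not given in the sources used here, and detection calls were not used here. The deposited Ye6100 table joins the 4 chips of each sample in 1 column, per the file headers.

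Samples were grouped by the genotype in the labels into 3 ARV1 mutant samples (mutants 1 and 2 on Ye6100, mutant 3 on S98) and 2 controls. The 4 chips of a Ye6100 sample counted as 1 replicate. The deposited signals have 2% trimmed means within 10% of each other on Ye6100 and were used as they stand. On S98 they differ, so control 3 was multiplied by 0.707 and mutant 3 by 1.41. Signals under the 5th percentile of a table (2.4 on Ye6100, 1.98 on S98) were raised to it, and log2 was taken. A gene was tested when the mean signal of its brightest probe set exceeded the 25th percentile of the table in both tables (25.4 and 28.1). That probe set gave the gene's value. Signals listed at 0 number 0, 2 and 1 in control 1/2, mutant 1 and mutant 2, and 15 and 17 in control 3 and mutant 3.

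Of 6593 Ye6100 probe sets 6421 are named by an open reading frame, and 5837 of these matched a locus tag of the reference gene table (assembly R64), giving 5659 genes. Of 9335 S98 probe sets 6504 have 1 gene symbol in the platform annotation, 328 have several and 2503 have none, giving 5656 genes. Both tables name 5315 genes, and 4287 were tested.

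The main test was limma (version 3.58.1, R version 4.3.3), with lmFit and eBayes with a trend, on genotype with the array format as a block. The format is the same split as the pairing by replicate number in the labels and by the control each mutant was compared with. Adjustment was by Benjamini-Hochberg at 0.05. The fit leaves 2 residual degrees of freedom. Genes at least 2-fold changed the same way in all 3 mutants were counted without a test. Of 33 gene lists 31 had at least 3 tested members, a minimum set after the data were seen, and were tested with limma's camera, two-sided, at a preset correlation of 0.01, with an estimated correlation, with fry, and against 10000 random lists matched on signal. With an estimated correlation camera takes the 2 residual degrees of freedom, and fry also rests on them, while the preset form takes far more. The shared control of mutants 1 and 2 was simulated in 20 runs, with the same variance for each sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

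The groups, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes ARV1, then the 12 highest and 12 lowest genes past the threshold and, where these are too few, the genes with the largest smallest ratio over the 3 mutants. It adds up to 4 members per list with the largest fitted change, and KAR2, PDI1, HAC1, INO1, ARE1, ARE2, ERG11 and HMG1. For the isolates it takes the 10 largest differences each way. Other genes are named because a test over their list called them, as markers, or for their place next to ARV1, and they were chosen after their values were seen. Alternatives covered scaling, floor, filter, probe set choice, block, trend, threshold and leaving out each sample. Leaving out genes listed at 0, leaving out cross-hybridising probe sets, and array weights were added after seeing the data.

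The scripts were tested on simulated data for the mutant and control comparison over 4287 genes, with 200 genes changed in each of 10 runs. Of genes changed by 1, 2 and 3 on the log2 scale, 5.37%, 59.1% and 91.8% were called. Over all runs 67 of 1110 calls were false. With the preset correlation, 94% of lists shifted by 0.5 were called, and 0% of lists without a shift. The estimated correlation and fry were not tried on simulated data. In these runs genes varied independently and all samples had the same variance. The estimated correlation in the data was 0.66 for ribosomal proteins and 0.57 for the phosphate regulon, so the shares for lists do not carry over to such lists.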

Results

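Transcript levels were measured in 5 RNA samples of budding yeast (Saccharomyces cerevisiae, background W303, mating type a), 3 from ARV1 mutants and 2 from controls. ARV1 encodes a membrane protein of the endoplasmic reticulum (ER) that is linked to lipid transport. Cells were in mid-logarithmic growth in rich glucose medium. On the older array format, Ye6100, each sample was spread over 4 chips. That format held 1 control (strain SCY328, here control 1/2), mutant 1 (isolate SCY820) and mutant 2 (isolate SCY840). The single-chip S98 format held control 3 (strain SCY2004) and mutant 3 (isolate SCY840). Each mutant was compared only with the control of its own format. The 2% trimmed mean signal was 250.1, 249.7 and 249.7 on Ye6100 for control 1/2, mutant 1 and mutant 2. On S98 it was 500.3 for control 3 and 250.1 for mutant 3, before both were brought to a common value. The labels do not say how many separate cultures were grown, so p-values measure the spread between these samples, and the number of arrays limits the precision.

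The ARV1 transcript (YLR242C) was low in every mutant sample. On Ye6100 its signal was 33.4 in the control, 1.0 in mutant 1 and 2.2 in mutant 2. Both mutant signals lay under the floor of 2.4, which puts ARV1 at least 13.9-fold lower there. On S98 the scaled signal was 51.8 in control 3 and 6.79 in mutant 3, which was 7.63-fold lower. ARV1 lay under the signal filter, and in the fit of all 5315 shared genes its log2 change was -3.43 ± 0.42 (SE), with a limma adjusted p of 0.326. Mutants 1 and 2 entered that fit at the floor, so the change is a bound and the SE leaves out their spread. Where the probes lie relative to the mutated part of the gene is not given in the sources used here.

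The first comparison asked which transcripts differ between ARV1 mutants and controls. The highest fitted change belonged to ULI1 (YFR026C), known as a target of the unfolded protein response. Its log2 ratio was 6.25, 6.67 and 4.88 in mutants 1, 2 and 3, a fitted change of 5.78 ± 0.49 (SE, 3 mutants and 2 controls). SIL1, a nucleotide exchange factor for the ER chaperone Kar2, had a fitted log2 change of 2.47 ± 0.36, and ERO1, the oxidase that drives disulfide formation in the ER, 2.06 ± 0.34. GSC2, a subunit of the cell wall glucan synthase, had 3.29 ± 0.43. At the low end stood SPL2 and PHO5, genes of the phosphate starvation response, at -3.61 ± 0.55 and -3.54 ± 0.76. None of these genes passed the test over all genes.

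Of 4287 genes tested, limma called 0 at an adjusted p under 0.05. The smallest adjusted p was 0.125, for ULI1. At an unadjusted p under 0.05 there were 281 genes, 233 higher and 48 lower in mutants, where chance alone gives 214.4. A change of at least 2-fold in the same direction in all 3 mutants was seen for 101 genes, 89 higher and 12 lower. Independent lists of the sizes seen on the 2 formats would share 20.4 higher and 0.851 lower genes. With log2 values centred on the table median the split was 62 higher and 22 lower. The median log2 ratio over all genes was 0.24 in mutant 1, -0.04 in mutant 2 and 0.13 in mutant 3. The median fitted log2 change was 0.096, and camera compares each list with the other genes, not with 0. The number of calls depended on mutant 2. Without it, limma called 669 genes, 571 higher and 98 lower, of which 439 (65.6%) had a ratio of the same sign in mutant 2. Over all genes 59.6% had the same sign in mutants 1 and 2. Unchanged samples against their shared control gave 66.7% in a simulation with equal variance in all samples. In both remaining mutants 256 genes passed 2-fold. Without mutant 1 limma called 30 genes, and without mutant 3 or control 3, which leaves Ye6100 alone, 0 genes, with 58 at an unadjusted p under 0.05. The 2-fold count was then 261, and it was 492 for S98 alone without control 1/2.

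The 12 genes with the highest smallest ratio over the 3 mutants were ULI1, RTA1, GSC2, HOP1, MEC1, YNR065C, SIL1, THI21, YIL108W, ERO1, CRG1 and DAL4. RTA1, linked to resistance to a toxic sterol analogue, had log2 ratios of 2.78, 3.15 and 2.75 in mutants 1, 2 and 3. HOP1, a component of meiotic chromosomes, had 2.55, 3.06 and 3.21, from a Ye6100 control signal of 8.8. YNR065C, a sortilin-like open reading frame, had a fitted log2 change of 2.94 ± 0.42, and THI21, of the thiamine pathway, 2.68 ± 0.38. The checkpoint kinase gene MEC1 had 2.81 ± 0.37 from its brightest probe set and 1.70 from the mean of all its probe sets, which disagreed in sign on S98. Probe sets of NCR1, AUS1, HAC1 and RPP1B, reported below from the brightest, also disagreed, and their means gave 1.16, 0.70, 0.66 and -0.51. For YIL108W, CRG1 and the allantoin permease gene DAL4 the fitted log2 change was 2.35 ± 0.36, 2.10 ± 0.36 and 2.21 ± 0.36. MEC1 and THI21, like HOP1, had Ye6100 control signals under the filter of 25.4, at 22.6 and 24.6. Over these 12 genes limma's adjusted p lay between 0.125 and 0.372.

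**Figure D1:**
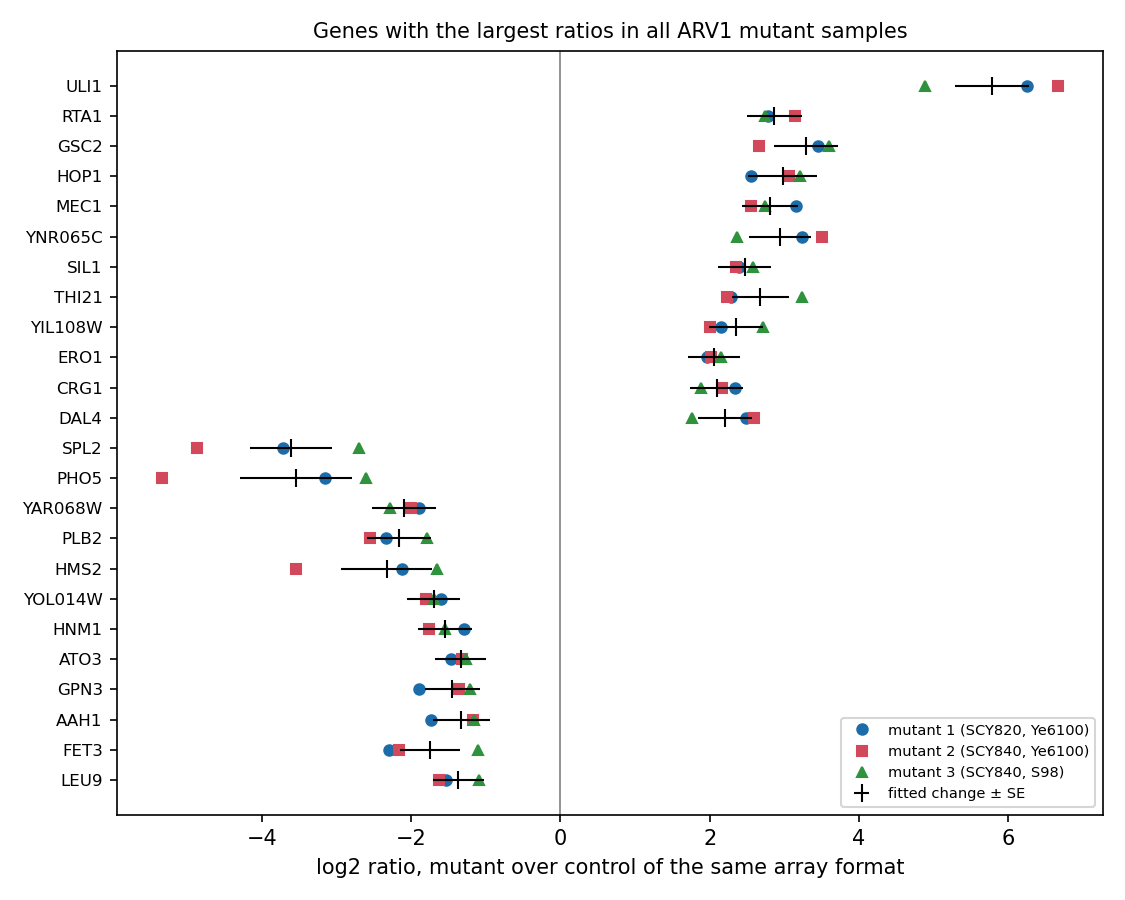
Log2 ratio of mutant over control of the same array format (horizontal axis) for the 12 genes with the highest and the 12 with the lowest ratios shared by all 3 mutants (vertical axis), with symbols for the 3 mutant samples and black bars for the fitted change ± SE. ULI1 lies at 6.25, 6.67 and 4.88, and SPL2 at -3.71, -4.87 and -2.71.

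The 12 genes at the other end were SPL2, PHO5, YAR068W, PLB2, HMS2, YOL014W, HNM1, ATO3, GPN3, AAH1, FET3 and LEU9. SPL2, which restrains low-affinity phosphate uptake, had log2 ratios of -3.71, -4.87 and -2.71. The acid phosphatase gene PHO5 had -3.15, -5.34 and -2.61. For HNM1, the choline transporter gene, the ratios were -1.30, -1.77 and -1.55, and for FET3, the multicopper oxidase of high-affinity iron uptake, -2.29, -2.16 and -1.11. PLB2, a phospholipase B gene, had a fitted log2 change of -2.17 ± 0.43, HMS2 -2.33 ± 0.61 and YAR068W -2.09 ± 0.43. The probe sets of YAR068W are marked as cross-hybridising on both formats, so its value may include other genes. The same holds on S98 for CRG1, DER1 and RPS26A. YOL014W, ATO3, AAH1 and LEU9 had -1.70 ± 0.36, -1.34 ± 0.34, -1.33 ± 0.38 and -1.37 ± 0.34. GPN3, which lies next to ARV1, had -1.45 ± 0.37. Limma's adjusted p for these 12 genes lay between 0.333 and 0.641.

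Genes for protein folding in the ER stood higher in the mutants than other genes did. Of 16 tested members of this list 11 were higher in all 3 mutants and 0 were lower in all 3, and the median fitted log2 change was 1.05. Over all tested genes 26.2% were higher and 14.6% lower in all 3 mutants, shares to set beside the counts of every list. The list shift had a camera adjusted p of 9.2e-07 with the preset correlation. The call was lost with adjusted p = 0.497 with an estimated correlation. That estimate was 0.0052, under the preset 0.01, so a higher correlation did not lose the call. With an estimated correlation camera tests on the 2 residual degrees of freedom, and with the preset one on far more. The unadjusted p was then 0.031, the smallest of the 31 lists. This setting, here and below, therefore cannot tell an unshifted list from too few degrees of freedom. None of the members was called over all genes, and 5 were called higher adjusted over the list alone, namely SIL1, ERO1, LHS1, EUG1 and MPD1. The chaperone gene LHS1 had a fitted log2 change of 1.51 ± 0.38, and the protein disulfide isomerase family genes EUG1 and MPD1 had 1.33 ± 0.34 and 1.37 ± 0.37. JEM1, an ER DnaJ protein gene, had 1.72 ± 0.67, and PDI1 itself 1.19 ± 0.45. HAC1, which encodes the transcription factor of the unfolded protein response, had 0.72 ± 0.36. The chaperone gene KAR2 had log2 ratios of 0.66 and 0.90 on Ye6100 and -0.45 on S98.

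Genes for ER-associated degradation, GPI anchor synthesis and the cell wall were also called higher as lists. For ER-associated degradation 8 of 16 genes were higher in all 3 mutants, the median log2 change was 0.51, and camera gave an adjusted p of 0.00736 but adjusted p = 0.497 with an estimated correlation. DER1 led it at 2.24 ± 0.40 and was the 1 member called adjusted over the list alone, against 0 over all genes. USA1, DFM1 and UFD1 had 1.04 ± 0.39, 1.03 ± 0.39 and 0.81 ± 0.35. For GPI anchor synthesis 12 of 21 genes were higher in all 3 mutants, with a median of 0.44, a camera adjusted p of 0.00736 and adjusted p = 0.497 with an estimated correlation. MCD4, an ethanolamine phosphate transferase gene, had 2.01 ± 0.39 and was the 1 member called adjusted over the list alone, against 0 over all genes, while SPT14, GPI10 and GPI14 had 1.60 ± 0.39, 0.96 ± 0.36 and 0.82 ± 0.37. In the cell wall list 13 of 22 genes were higher in all 3 mutants, the median was 0.72, and camera's adjusted p was 1.1e-04, with adjusted p = 0.602 with an estimated correlation. Its median was 1.09, 0.09 and 0.93 in mutants 1, 2 and 3. GSC2, KTR2, KDX1 and CHS3 were the 4 members called adjusted over the list alone, against 0 over all genes, and KTR2, KDX1 and PIR3 had fitted changes of 2.73 ± 0.55, 1.99 ± 0.44 and 2.52 ± 0.82. KDX1 had a low Ye6100 control signal of 11.6. Without mutant 3 or control 3 camera's adjusted p was 0.0849 for ER-associated degradation and 0.0672 for GPI anchor synthesis. Without mutant 2 it was 0.0543 for GPI anchor synthesis.

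The phosphate regulon and ribosome biogenesis were the lists with the strongest shift to lower values. Of 11 phosphate genes 9 were lower in all 3 mutants, the median log2 change was -0.88, and camera gave an adjusted p of 3.8e-08, with adjusted p = 0.514 with an estimated correlation. SPL2, PHO5 and VTC4 were the 3 members called lower adjusted over the list alone, against 0 over all genes. VTC4, a polyphosphate polymerase subunit gene, had -1.46 ± 0.39, and the phosphate transporter gene PHO84 had log2 ratios of -0.70, -3.33 and -0.61. In ribosome biogenesis 19 of 26 genes were lower in all 3 mutants, with a median of -0.62, a camera adjusted p of 3.8e-08 and adjusted p = 0.548 with an estimated correlation. DBP2, DBP3, MPP10 and IMP3 had -0.94 ± 0.50, -0.92 ± 0.42, -0.92 ± 0.42 and -0.86 ± 0.36, and 0 members were called adjusted over the list alone or over all genes.

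Cytosolic ribosomal protein genes, glycolysis, ergosterol synthesis and the a-cell genes were called lower with smaller shifts. The median of 69 ribosomal protein genes was -0.66, 0.18 and -0.25 in mutants 1, 2 and 3. Their camera adjusted p was 1.1e-04, with adjusted p = 0.667 with an estimated correlation, and without mutant 1 the median was 0.026. RPS26A and RPP1B had fitted log2 changes of -1.14 ± 0.49 and -0.98 ± 0.42, RPP0 had 0.99 ± 0.74, and RPL22A is listed at 0 in control 3. For 16 genes of glycolysis and fermentation the median was -0.34 and camera's adjusted p 0.00209, with adjusted p = 0.497 with an estimated correlation. PGK1 and ENO1 had -1.05 ± 0.43 and -0.74 ± 0.39, PDC5 had 1.06 ± 0.36, and TDH3 is listed at 0 in mutant 3. For 24 ergosterol genes, 7 lower and 2 higher in all 3 mutants, the median was -0.20 and camera's adjusted p 0.0152, with adjusted p = 0.497 with an estimated correlation. ERG4 had log2 ratios of -0.28, -1.43 and -0.81. ERG3 and ERG24 had fitted changes of -0.75 ± 0.40 and -0.60 ± 0.35, while HMG2 had 0.94 ± 0.33, HMG1 -0.16 ± 0.41 and ERG11 -0.26 ± 0.35. For 10 a-cell and pheromone response genes the median was -0.25 and camera's adjusted p 0.0146, with adjusted p = 0.497 with an estimated correlation. MFA2, STE2, FAR1 and AGA2 had -1.12 ± 0.35, -1.05 ± 0.35, -0.92 ± 0.54 and -0.70 ± 0.35. In these 4 lists 0 members were called adjusted over the list alone or over all genes. Without mutant 1 camera's adjusted p was 0.992 for ribosomal proteins and 0.0650 for the ergosterol and the a-cell list, and without mutant 3 or control 3 it was 0.0849 and 0.0823 for the latter pair. With quantile normalization it was 0.768 for ribosomal proteins, 0.229 for glycolysis and 0.103 for ergosterol synthesis. Against random lists matched on signal, at an unadjusted 0.05, 10 lists stood out, 5 higher and 5 lower. Ergosterol synthesis and the a-cell list were not among them, with a lower median in 3.10% and 2.60% of random lists. Vacuolar hydrolases and autophagy (99.6%) and amino acid synthesis (2.00%) were.

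**Figure D2:**
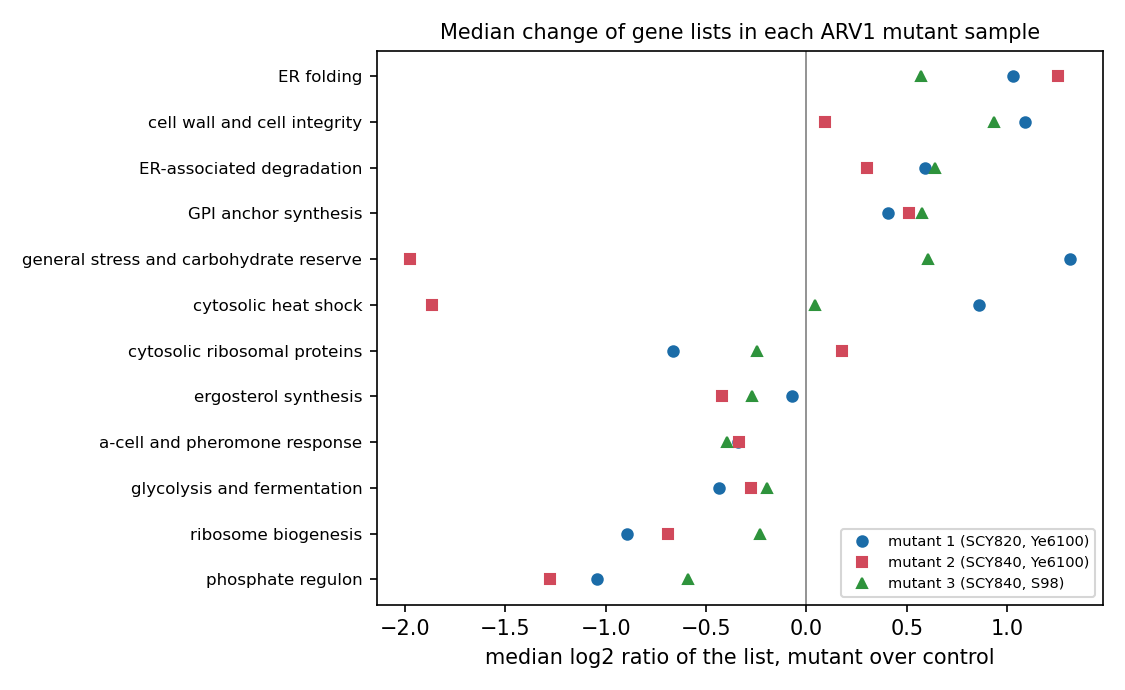
Median log2 ratio of mutant over control (horizontal axis) for the 10 lists that camera called with its preset correlation and for the 2 stress lists it did not call (vertical axis), with a symbol for each of the 3 mutant samples. The ER folding list lies at 1.03, 1.26 and 0.57, and the general stress list at 1.31, -1.98 and 0.61.

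Among lipid genes outside ergosterol synthesis no list was called by camera. ARE1, a sterol acyltransferase gene, had a fitted log2 change of 1.82 ± 0.48, and ARE2, the other such gene, 0.08 ± 0.40, which was -0.082 with median centring and -0.049 with quantile normalization. NCR1, the yeast relative of the Niemann-Pick C1 gene, had 1.60 ± 0.41, and the steryl ester hydrolase gene YEH1 1.25 ± 0.39. The camera adjusted p of that list, sterol esters, neutral lipid and sterol transport, was 0.369. INO1, which makes inositol phosphate, had log2 ratios of 2.66, 1.23 and 2.92, and GPT2 had a fitted change of 1.94 ± 0.50, in a phospholipid synthesis list with an adjusted p of 0.634. AUS1 and DAN4 had 1.58 ± 0.46 and 1.81 ± 0.55 in the list of sterol uptake and hypoxic genes, whose adjusted p was 0.860. The Ye6100 control signals of INO1, GPT2 and AUS1 were 11.5, 20.6 and 16.1, under the filter of 25.4, so their ratios start from a low level. Sphingolipid metabolism had an adjusted p of 0.377, fatty acid synthesis 0.356 and peroxisomal beta-oxidation 0.293. The sphingolipid list had a median of 0.05 and a mean of 0.03, and the phospholipid list a median of -0.08 and a mean of 0.14. Camera placed both lower than other genes, and the median over all tested genes was 0.096. SPS19, at 1.71 ± 0.32, was the 1 gene of these lists called adjusted over the list alone, against 0 over all genes.

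The other secretory pathway lists were not called either, with camera adjusted p of 0.356 for N-glycosylation, 0.128 for protein O-mannosylation, 0.265 for ER translocation and 0.0913 for ER-Golgi vesicle transport. PMT3, a mannosyltransferase gene, had 1.74 ± 0.41 and was called adjusted over the list alone, against 0 over all genes. SEC72 had 1.21 ± 0.36, ALG7 0.75 ± 0.38 and SEC24 1.24 ± 0.49. Pleiotropic drug resistance had a camera adjusted p of 0.0861, and RTA1 was its 1 member called adjusted over the list alone, against 0 over all genes. The iron regulon, which holds FET3 and FIT2 at -1.75 ± 0.41 and -1.14 ± 0.45, had 0.0644. Amino acid synthesis had 0.0706, vacuolar hydrolases and autophagy 0.161, the vacuolar ATPase 0.369, oxidative stress 0.369, respiration and the TCA cycle 0.241, and cell cycle and histones 0.241. ARG1, AMS1 and PCL1 had -1.46 ± 0.54, 1.96 ± 0.79 and 1.72 ± 0.55, with a low Ye6100 control signal of 18.2 for PCL1. The laboratory marker genes had 0.466, with URA3 at -0.74 ± 0.37. Of the meiosis list only HOP1 passed the signal filter, and of the alpha-cell list 0 genes did. The 4 alpha-cell genes had Ye6100 signals between 3.5 and 27.9. Their scaled S98 signals in control 3 and mutant 3 were 42.6 and 19.4 for MF(ALPHA)1, 45.7 and 21.5 for MF(ALPHA)2, 43.3 and 76.5 for STE3, and 36.6 and 54.5 for SAG1.

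The ratios of stress genes differed between the mutant samples. The median log2 ratio of 16 general stress and carbohydrate reserve genes was 1.31 in mutant 1, -1.98 in mutant 2 and 0.61 in mutant 3, and that of 18 cytosolic heat shock genes 0.86, -1.87 and 0.04. HSP26, a small heat shock protein gene, had 2.06, -4.77 and 0.04, and PGM2, for phosphoglucomutase, 1.20, -3.91 and 0.20. NTH1, a trehalase gene, had 1.74, 1.07 and 1.03, and SSA1 is listed at 0 in control 3. Camera's adjusted p was 0.944 for the general stress and 0.249 for the heat shock list. It placed both lower than other genes, as it did the oxidative stress and laboratory marker lists. Their mean fitted change was 0.12, 0.01, 0.01 and 0.01, beside a median of 0.096 over all tested genes. The ratio of 5' to 3' signal for ACT1, the actin gene, was 0.781 in control 1/2, 0.764 in mutant 1 and 0.351 in mutant 2, and 1.15 and 1.17 in control 3 and mutant 3. For SPT15 it was 0.563, 0.603 and 0.370 on Ye6100 in the same order, and 0.518 in control 3 and 0.296 in mutant 3. For SRB4 it was 0.691, 0.399 and 0.201, and 0.403 in control 3 and 0.274 in mutant 3. The median signal of 18S ribosomal RNA probe sets on Ye6100 was 740.0, 212.1 and 78.9 in control 1/2, mutant 1 and mutant 2, and on S98 65.7 in control 3 and 113.8 in mutant 3. That of 25S probe sets was 866.2, 374.4 and 91.2 on Ye6100, and 207.8 in control 3 and 165.3 in mutant 3.

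The next comparison asked how alike the 3 mutant samples were. Across 4287 genes, which are not independent replicates, the log2 ratios of mutants 1 and 3 correlated with Pearson's r of 0.590 and Spearman's rho of 0.592, and 72.1% of genes had the same sign. For mutants 1 and 2, which share a control, r was 0.275 and rho 0.263. Unchanged samples against a shared control gave 0.498 in simulation. The covariance of that pair was 0.216, beside a simulated 0.282. The simulation gave all samples the same variance, while array weights were 0.155 for mutant 2 and 1.59 for control 1/2 and mutant 1. The simulated values therefore do not show whether mutants 1 and 2 agree less than unchanged samples would. For mutants 2 and 3, both of isolate SCY840, r was 0.120, rho 0.058, and 49.9% of genes had the same sign.

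Isolates SCY840 (mutant 2) and SCY820 (mutant 1) were compared on Ye6100, with 1 sample each and no test. The 5' to 3' ratios of ACT1, SPT15 and SRB4 were all lower in mutant 2, so isolate and RNA sample cannot be told apart here. For ACT1 the 5' signal was 2503 in mutant 1 and 1172 in mutant 2. For SPT15 it was 226.9 and 204.4 (SD over 4 chips 36.6 and 27.4), and the 3' signal was 376 and 553. The 5' signals of SRB4, 18.8 and 10.2, lay under the filter of 25.4. TCA17, BIL1 and RPA12 stood highest in mutant 2, with log2 differences of 2.76, 2.65 and 2.37. In mutant 3, the other SCY840 sample, their log2 ratios to control 3 were -1.60, -1.18 and -1.18. HSP26 and MGA1 were lower in mutant 2, at -6.82 and -5.89, and had ratios of 0.04 and 1.11 in mutant 3. YNL194C and SSA3 had signals of 358.4 and 241.5 in mutant 1 and lay under the floor in mutant 2, so that their log2 differences of -7.22 and -6.65 are bounds. At least a 2-fold difference was seen for 1360 genes, 343 higher and 1017 lower in mutant 2. With quantile normalization the split was 646 higher and 632 lower. The median log2 difference over all genes was -0.25. Ribosomal protein genes had a median difference of 0.91, higher in 65 of 69 genes, and general stress genes -3.35, lower in 16 of 16. The share of random lists matched on signal with a lower median was 100% and 0%. It was 0% also for heat shock and for respiration and the TCA cycle. The share treats genes of a list as independent and is no test of the isolates. In the main fit the estimated correlation was 0.66 for ribosomal proteins and 0.97 for general stress genes.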

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

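All tests in this part were chosen after the results were seen, and none of the differences between isolates or formats was tested.

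The cytochrome c isoform gene CYC7 was the 1 gene at least 2-fold changed one way in the SCY820 sample (log2 ratio 1.05) and at least 2-fold the other way in both SCY840 samples (-2.54 and -1.23). PUN1 was the 1 gene at least 2-fold higher in both Ye6100 comparisons (1.75 and 1.60) and at least 2-fold lower on S98 (-1.01). Outside the genes compared, 33 Ye6100 probe sets were at least 2-fold higher in both mutants than in the control and 37 were lower, of 460 above the filter. Among S98 probe sets outside the comparison 124 were at least 2-fold higher in the mutant and 117 lower, of 1624.

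Stress and heat shock genes were lower in mutant 2 than in its control. In mutant 2 the median log2 ratio was -1.98 for the general stress genes and -1.87 for the heat shock genes. In mutant 3, the same isolate, it was 0.61 and 0.044 (bootstrap SD 0.237). The controls differ, SCY328 for mutant 2 and SCY2004 for mutant 3, as do the formats. A low level in SCY2004 could hide a fixed low level in SCY840, so these ratios cannot decide on a difference between isolates. Relative to mutant 1, the 5' signal in mutant 2 was lower for ACT1, within the spread over chips for SPT15, and under the filter for SRB4. A 3' bias stays open as a cause. Over 34 genes the median of mutant 2 relative to mutant 1, -3.05, lies beyond the largest 5' loss of 3 control genes, -1.09 for ACT1. The 34 genes were themselves higher in mutant 1, with a median log2 ratio of 1.22. Against the control their median in mutant 2 was -1.89 (bootstrap SD 0.31). ACT1 had 5' signals of 2909 in control 1/2 and 1172 in mutant 2. Losses in 3 genes cannot bound the loss in others. A sample that is not an ARV1 mutant is argued against by the ARV1 signal of 2.2 beside 33.4 in the control and an ER folding median of 1.26. A difference in the state of the culture at harvest may account for the pattern, but no test of it was run.

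Both neighbours of ARV1 had ratios of one sign in all 3 mutants, CSC1 with log2 ratios of 1.84, 1.39 and 1.43, and GPN3 with -1.89, -1.36 and -1.21. Among 3152 loci with both neighbours tested, 0 others had neighbours as far from 0, where 0.538 loci are expected from the share of such genes, too few to decide whether the neighbours are drawn from the genome-wide response. Chance values of the control shared by mutants 1 and 2 stay open too, since 6.79% of genes lay as far from 0 on S98 as the lesser neighbour, a share for 1 neighbour and not for both. Without mutant 2, where no control is shared, both were called (adjusted p = 0.00126 and 0.00229), but so were all 101 genes at least 2-fold changed in all 3 mutants, so the call follows from the pattern. An effect of the mutation at the locus on nearby transcripts may account for it and was not tested.

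Genes of chromosome XIV were lower than other genes, by a median log2 of -0.24, -0.40 and -0.08 in mutants 1, 2 and 3, and genes of chromosome XVI higher, by 0.17, 0.33 and 0.12. Over 16 chromosomes the Ye6100 deviations correlated with those on S98, with r = 0.727 (permutation p = 0.00103) and rho = 0.829 (permutation p = 1.6e-04), and r was 0.664 without chromosomes XIV and XVI (permutation p = 0.00902). These permutations test against no correlation. Ratios of single genes also correlated between formats, with r of 0.590 for mutants 1 and 3 and 0.120 for mutants 2 and 3. Medians of any grouping of genes would then tend to correlate, so Ye6100 chips scaled apart stay open as a cause. A gained or lost chromosome in all cells needs a deviation near 1 on the log2 scale, and the largest was 0.401. A chromosome gained in part of the cells, or gene content that differs between chromosomes, stays open, and no biological explanation was tested.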

How the results depend on the processing

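Array weights, and leaving out genes listed at 0 or cross-hybridising probe sets, were chosen after the data were seen. No cause was tested for the values below, except that fewer samples, a looser threshold or fewer degrees of freedom follow from the setting. Signal near background and 2 residual degrees of freedom limit the fit, and fits without 1 sample assume that a lone sample varies like the others.

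The count of genes called by limma was 0 in the main fit, 1 with quantile normalization, 427 with array weights, which give mutant 2 a weight of 0.155, and 1 with no replicate block. The setting with no block also quantile-normalized all 5 samples together across the formats. Leaving out 1 sample gave 0 to 669 genes. Under the other settings it was 0, with 185 to 338 genes at an unadjusted p under 0.05 over both formats, and 58 on Ye6100 alone. The 2-fold count of 101 genes was 309 at 1.5-fold and 26 at 3-fold, and 127 to 492 without 1 sample. Camera called 10 lists with the preset correlation, 0 with an estimated correlation, 0 with fry and 6 to 14 without 1 sample, and random lists gave 10, 5 higher and 5 lower. The estimated correlation and fry rest on 2 residual degrees of freedom. Their smallest unadjusted p over the 31 lists was 0.031 and 0.0073, so 0 calls there cannot by themselves decide against a list. The estimated correlation lay under the preset of 0.01 for ER folding (0.0052), ER-associated degradation (-0.013) and GPI anchor synthesis (-0.033). The same held for ergosterol synthesis (-0.024), glycolysis (-0.047) and the a-cell list (-0.11). It lay above for the cell wall (0.38), phosphate regulon (0.57), ribosome biogenesis (0.41) and ribosomal proteins (0.66). The isolates differed at least 2-fold in 1360 genes, and in 845 with a filter at the 50th percentile. With the preset correlation kept, 6 of the 10 called lists were lost under another scaling or without 1 sample.

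Of 147 named genes 13 changed sign under some setting, none of them called there. ARE2 went from 0.083 to -0.082 with median centring and -0.049 with quantile normalization. On Ye6100 alone SSA1, RPL22A, RPP0, CAN1 and ARE2 had -0.82, -0.42, -0.30, -0.18 and -0.21. With array weights HSP26, PGM2, HXK1 and MDH1 had 0.76, 0.48, 0.57 and 0.037. Without 1 sample the range was -0.45 to 0.026 for the median of cytosolic ribosomal proteins, -0.35 to 2.98 for SSA3, -1.30 to 0.015 for INO2, -2.36 to 1.05 for HSP26, -1.86 to 0.70 for PGM2, -1.57 to 0.78 for HXK1, -1.09 to 0.053 for GSH1, -1.04 to 0.14 for MDH1 and -0.49 to 0.018 for HMG1. It was -0.82 to 3.02 for SSA1, -0.42 to 4.90 for RPL22A, -0.30 to 1.38 for RPP0, -0.18 to 0.88 for CAN1 and -0.21 to 0.17 for ARE2. Array weights called 75 named genes, and fits without mutant 2 and without mutant 1 called 86 and 22.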

Other observations

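The values in this part were chosen after they were seen and were not tested. Among Ye6100 probe sets that have no partner on S98 in the comparison, one of YPR077C had signals of 57.2, 521.4 and 793.4 in control 1/2, mutant 1 and mutant 2. DOG2, a 2-deoxyglucose-6-phosphate phosphatase gene, had 72.0, 338.0 and 277.4. DDI2 and DDI3, near-identical genes whose probe sets are marked as shared by a gene family, had 8.0, 59.6 and 71.7, and 7.7, 62.2 and 59.7. On S98 NCW1 had a deposited signal of 3572.6 in control 3 and 187.6 in mutant 3, a log2 ratio of -3.25 after scaling. Probe sets of the 5S ribosomal RNA genes RDN5-1 and RDN5-3 had -2.19 and -2.01, and the small nucleolar RNA gene SNR63 had -2.17.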
